A study of Mus musculus with 16 samples.

How the data were processed

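PolyA RNA from the right and left ventricular free walls of male FVB mice with pulmonary artery banding (read from the label PS) or a sham operation was sequenced in 16 libraries, 4 per group. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, aligned to mm9 with STAR 2.5.3a and quantified with Cufflinks 2.2.1, with R 3.3.1 used afterwards. The deposited values are FPKM for each of 23946 genes in each library. Counts were not used here. The authors' table of group values differs from the mean of the replicates (median ratios 0.667 to 0.894), so group means were computed from the libraries.

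Values were analysed as log2(FPKM + 1) for the 12100 genes at 1 FPKM or more in at least 4 of 16 libraries. A single limma 3.58.1 fit of 4 group means (R 4.3.3, trended prior) gave 5 comparisons: banded against sham in each ventricle, the difference between these effects, and right against left in sham and in banded mice. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a comparison, with a threshold of 0.05. They measure the spread between these samples, which may be technical. The same fit was run on values divided by a scale factor per library, the median ratio to the geometric mean library over 8211 genes, and a gene counts as changed on both scales where it passed in the same direction in both. The groups, the comparisons, the threshold, the filter, the gene lists and the first set of alternatives were chosen before the data were examined. The use of both scales was decided afterwards.

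The genes named were chosen by a rule. For the right ventricle these were the 8 largest rises and 8 largest falls, and for the other comparisons 5 of each, among genes past the threshold with a group mean of at least 5 FPKM and no overlap between the libraries of the groups. Entries with several symbols, predicted genes, small RNA and pseudogenes were left out. For the difference between ventricles, the groups of either ventricle had to be free of overlap. The rule added 16 genes fixed in advance (Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Timp1, Ppargc1a, Esrra, Cpt1b, Pdk4, Ckmt2 and Slc2a1) and, for each list, up to 4 members with the smallest p-values, up to 2 per direction where both occur.

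Lists written from general knowledge, 40 gene lists and 15 marker lists with 872 symbols, of which 857 were in the table, were tested with limma camera at a preset correlation of 0.01 where at least 3 genes were tested, which left 48. Camera with an estimated correlation and fry were run beside it. No list call passed the threshold with an estimated correlation.

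The FPKM give no depth. Fragments per library were estimated as 3.42e+05 to 8.89e+06 from 3197 genes, with an assumed fragment length of 200 nt. The first peak among the lowest values of FPKM times transcript length was taken as 1 fragment. At 1 FPKM a transcript of the median length, 2789 nt, then rests on 0.886 to 23.0 fragments, and at 5 FPKM on 4.43 to 115. In simulated libraries of known depth, the depth was recovered at 0.963 to 1.07 of its true value. They were drawn with the same assumed fragment length, so this does not check that assumption. In a separate simulation that took the estimated depths as given, the right ventricular comparison as deposited found 36.4% of 2-fold and 81.5% of 4-fold changes, with 0.249% false calls. The left found 37.5% and 81.8%, with 0.191%. These simulations held no trend with transcript length. With a set length trend put into the simulated right ventricular banded libraries, 10.7% of unchanged genes were called, and 0.0792% after the correction for length and GC content. That trend was of a chosen size, in length only and the same in every banded library. These shares are therefore not the false call rates of the real data. With no gene changed and libraries drawn at their estimated depths and scale factors, a median of 8.5 genes were called as deposited in the right ventricle, 0 in the left, 1.5 for their difference, 5 between sham and 0 between banded ventricles. Rescaled, which leaves depth as the difference, the medians were 5.5, 0, 1.5, 7.5 and 0 in the same order. All genes were drawn with the same set spread and none changed, so these draws do not measure what scale factors did to the real counts. In the simulation with changed genes, 23 unchanged genes were called in the left ventricle as deposited and 1 rescaled. The real left count was 1764 as deposited and 485 rescaled.

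Alternatives were other pseudocounts, filters, scalings (TPM scaling, which brings every library to the same sum, and quantile normalization), a robust prior, fits to the libraries of a comparison only, a block by library number, and omission of each library. Added after the data were examined were library weights, rescaling with a filter at 5 FPKM, rescaling without small RNA, rescaling with each library corrected for its trend with transcript length and GC content (11573 genes with a length), rescaling with the block, and only libraries with an Rn45s value. The list medians under each scaling, the list tests among libraries with an Rn45s value and the matched lists on corrected values were also chosen afterwards. Transcript lengths and GC content came from GRCm38 annotation matched by gene name (22877 of 23946 genes), and positions were not used. Mitochondrially encoded genes were not among the genes of the table (0 of 13 symbols matched). Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.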

Results

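Right and left ventricular free walls of male FVB mice, an inbred strain, were taken after pulmonary artery banding, a narrowing of the vessel that raises the pressure load on the right ventricle, or after a sham operation. The comparison of the groups asks which transcripts differ in the pressure-overloaded right ventricle. PolyA RNA gave 16 libraries in 4 groups of 4, a sham and a banded group for each ventricle. The left ventricle, which the band does not load directly, gave the background measured the same way. The labels call the other group PS while the protocol names only banding and sham, so PS was read as banded. Banded libraries of both ventricles carry the names PS_9552, PS_9553, PS_9561 and PS_9564, and sham libraries the numbers 1 to 4. Right and left libraries with the same number mostly resembled each other no more than others did. The correlation across genes of their deviations from the group means lay between -0.0964 and 0.16 and exceeded 0.1 in 1 of 8 pairs. Only right library PS_9552 matched the left one of its own number best (0.16, highest other -0.00741). Genes are not independent replicates, and 4 libraries per group cannot show whether equal numbers mean the same mouse. The main fit used the numbers as names only, and a block by number was run as an alternative.

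The typical level of the deposited values differed between libraries. Rn45s, the ribosomal RNA precursor, was listed at 0 in 5 libraries, all from banded mice (left ventricle PS_9552, PS_9553 and PS_9561, right ventricle PS_9561 and PS_9564). The scale factors of these 5, each the median ratio of a library to the geometric mean of all libraries over 8211 genes, were 1.22 to 1.28, and those of the other 11 were 0.840 to 1.02. As deposited, the median log2 difference of the 12100 tested genes between banded and sham libraries was 0.26 in the right and 0.33 in the left ventricle. After division by the scale factors it was 0.11 and 0.01, after scaling every library to the same sum (TPM scaling) 0.65 and 0.18, and after quantile normalization -0.00745 and -0.0168. A single small RNA entry, Mir6236, held 21.3 to 59.7% of the sum that TPM scaling uses, so results with that scaling follow this entry too. A gene is described here as having risen or fallen where it passed the threshold in the same direction both as deposited and rescaled. No sham library was listed at 0 for Rn45s, so banding could be compared only among libraries with a value for it, which left 2 banded libraries of the right ventricle and 1 of the left. Depth also differed: the right ventricular sham libraries held an estimated 3.42e+05 to 1.37e+06 fragments and the right ventricular banded libraries 2.21e+06 to 6.13e+06, against 1.78e+06 to 4.33e+06 and 3.485e+06 to 8.89e+06 in the left ventricle. Genes with a value above 0 numbered 11055 to 13205 in the right ventricular sham libraries and 13984 to 15484 in the banded ones.

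**Figure D1:**
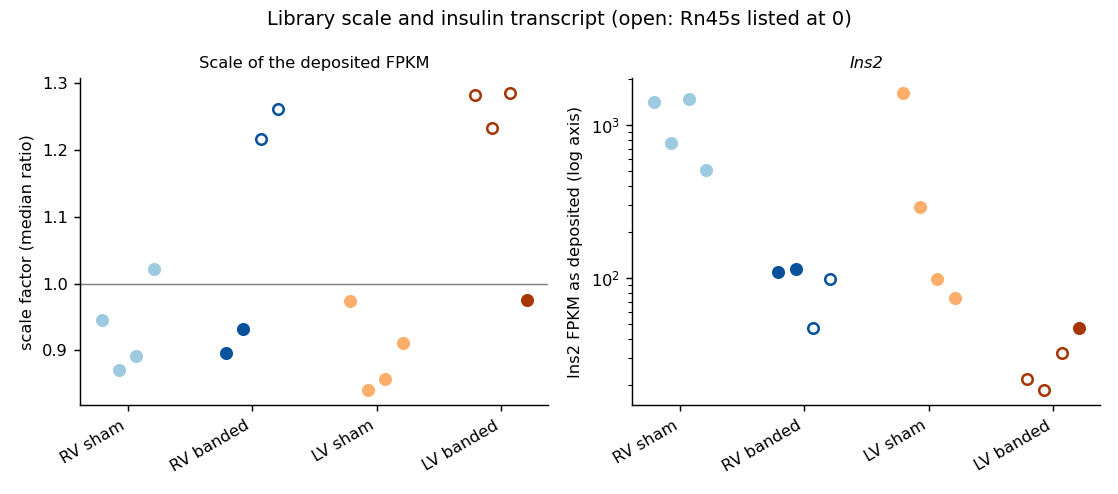
Scale factor of each library (left, ratio to the geometric mean library) and FPKM of the insulin transcript Ins2 (right, log axis) in the 4 groups, 1 point per library, with open points where Rn45s is listed at 0. The open points sit between 1.22 and 1.28 and all others between 0.840 and 1.02, and Ins2 was 509 to 1475 FPKM in the right ventricular sham libraries and 46.8 to 114 FPKM in the banded ones.

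In the banded right ventricle, natriuretic peptides and matrix genes showed the largest rises. Nppa, which encodes atrial natriuretic peptide, went from 65.8 ± 25.2 to 1976 ± 475 FPKM (mean ± SD, n = 4 per group, log2 change 4.94 ± 0.33 SE, limma adjusted p = 3.21e-07), a 30.7-fold rise as deposited and 26.8-fold rescaled. Nppb, encoding brain natriuretic peptide, rose from 114 ± 81.0 to 1024 ± 112 FPKM (log2 change 3.37, adjusted p = 0.000174). The secreted matrix proteins periostin and thrombospondin 4, encoded by Postn and Thbs4, rose from 3.51 ± 0.262 to 55.0 ± 19.2 FPKM and from 1.20 ± 0.550 to 25.2 ± 8.85 FPKM (log2 changes 3.58 and 3.55). Mfap4, a microfibril-associated protein, and Cilp, a matrix protein first described in cartilage, rose by log2 values of 3.21 and 3.05. Gdf15, a stress-induced cytokine, rose from 3.53 to 35.02 FPKM, and Ankrd1, a stretch-responsive sarcomere partner, from 389 to 3202 FPKM. Among the genes fixed in advance, Myh7 (beta myosin heavy chain) rose from 208 ± 33.8 to 547 ± 204 FPKM (log2 change 1.31, adjusted p = 0.00545). Acta1 (skeletal alpha actin) had a log2 change of 2.38 (adjusted p = 0.0097) with overlapping groups, since sham library 4 stood at 497 FPKM. The collagens Col1a1 and Col3a1 rose from 47.9 ± 7.63 to 101 ± 8.06 and from 41.8 ± 9.04 to 100.2 ± 7.55 FPKM. Timp1, an inhibitor of matrix metalloproteinases, rose by 2.30 (log2, adjusted p = 0.00371). Myh6, the main adult myosin heavy chain of the mouse, had a log2 difference of -0.21 (adjusted p = 0.472). Atp2a2, the sarcoplasmic reticulum calcium pump, had -0.24 (adjusted p = 0.377) and Ppargc1a, a coactivator of mitochondrial genes, 0.36 (adjusted p = 0.402). Slc2a1, a glucose transporter, passed only as deposited (log2 difference 0.84, adjusted p = 0.0167, rescaled 0.063).

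**Figure D2:**
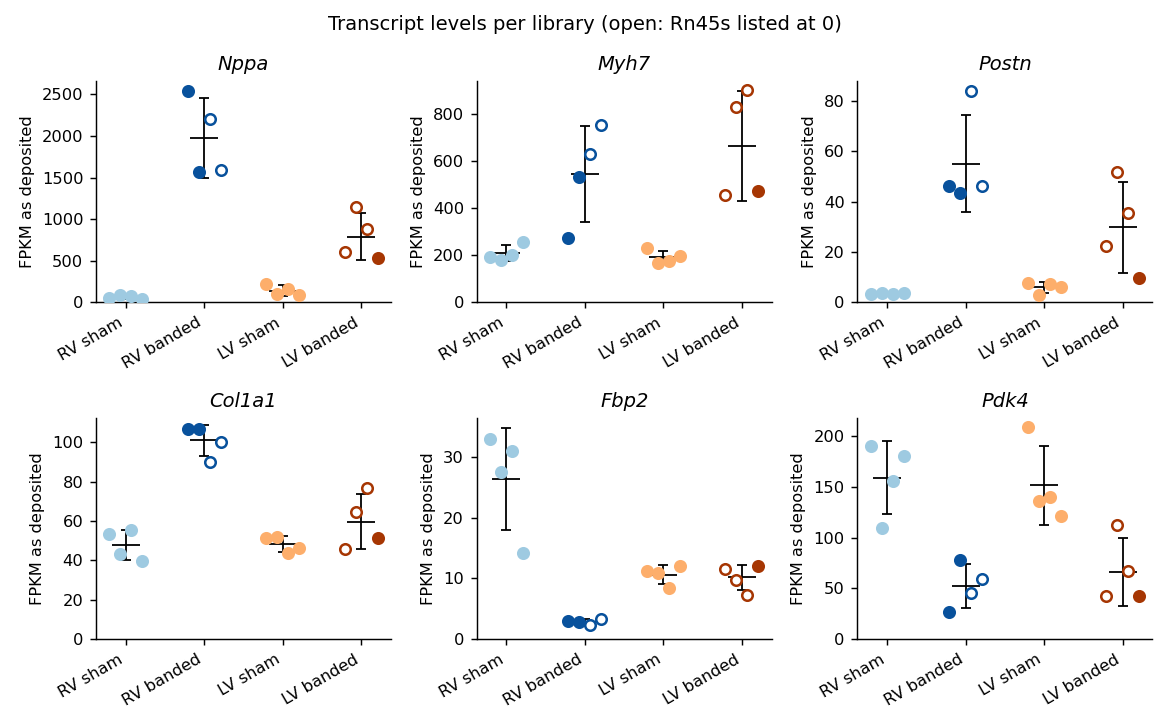
FPKM as deposited of 6 genes in the 4 groups, 1 point per library with mean and SD (n = 4), open points where Rn45s is listed at 0. Nppa averaged 65.8 FPKM in the sham and 1976 FPKM in the banded right ventricle, and Fbp2 26.4 and 2.88 FPKM.

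Of the 8 largest falls in the banded right ventricle 4 were in transcripts of pancreatic hormones. Fbp2, the muscle form of fructose bisphosphatase, fell from 26.4 ± 8.46 to 2.88 ± 0.401 FPKM (n = 4, log2 change -2.76 ± 0.23 SE, limma adjusted p = 5.45e-06). Of the genes fixed in advance, Pdk4, a kinase that inhibits pyruvate dehydrogenase, fell from 159 ± 36.1 to 52.5 ± 21.7 FPKM (log2 change -1.65). So did Esrra, a nuclear receptor for genes of energy metabolism, from 90.7 ± 11.04 to 50.9 ± 8.25 FPKM (-0.83). Cpt1b, also fixed in advance, which brings fatty acids into mitochondria, fell from 342 ± 33.3 to 246 ± 62.0 FPKM (-0.50). Ckmt2, the mitochondrial creatine kinase, passed only after rescaling (log2 difference -0.59, adjusted p = 0.00897; as deposited -0.40, adjusted p = 0.111). Lgals4, which encodes galectin 4, fell from 61.2 ± 13.1 to 12.1 ± 6.67 FPKM. Ins2 and Ins1, the insulin genes, fell from 1043 ± 478 to 92.7 ± 31.2 and from 268 ± 204 to 26.6 ± 11.9 FPKM. Gcg, encoding glucagon, fell from 32.1 ± 31.5 to 1.304 ± 0.473, Iapp, encoding amylin, from 33.1 to 3.81 and Resp18, a protein of neuroendocrine granules, from 10.8 to 0.888 FPKM. These hormones are made in pancreatic islets, and Ttr, another abundant islet transcript, was listed at 0 in all 4 right ventricular sham libraries. Hist1h4i, a histone gene, fell from 17.0 to 1.94 FPKM. Cpt1b lost its call without sham library 1, 3 or 4 or library PS_9552, PS_9553 or PS_9561 (highest adjusted p = 0.11), and Ins1 without sham library 3 or library PS_9561 (highest adjusted p = 0.06).

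Transcripts of oxidative phosphorylation (OXPHOS), the mitochondrial respiratory chain and ATP synthase, were lower in the banded right ventricle. Of 36 subunits of complex I tested, the NADH dehydrogenase, 21 fell and none rose (24 down and 1 up adjusted over the list alone). The median log2 change was -0.69 as deposited and -0.88 rescaled (limma camera adjusted p = 1.81e-18, adjusted p = 0.143 with an estimated correlation). Ndufs3 went from 272 ± 87.2 to 113 ± 16.9 FPKM and Ndufa13 from 514 ± 70.2 to 239 ± 30.9 FPKM (n = 4). In complex II, which oxidises succinate, 3 of 4 fell (3 over the list alone, adjusted p = 0.000105, adjusted p = 0.143 with an estimated correlation). Sdhc went from 950.1 ± 46.6 to 551 ± 23.0 FPKM. In complex III, 6 of 10 fell (6 over the list alone, adjusted p = 4.58e-06, adjusted p = 0.259 with an estimated correlation), among them Cyc1, cytochrome c1, by a log2 change of -0.94. In complex IV, cytochrome c oxidase, 8 of 12 fell (10 over the list alone, median -1.04, adjusted p = 2.21e-12, adjusted p = 0.143 with an estimated correlation). Cox7a1 went from 6252 ± 821 to 2260 ± 688 FPKM. Of 15 ATP synthase subunits, 11 fell (11 over the list alone, median -0.83, adjusted p = 1.95e-13, adjusted p = 0.143 with an estimated correlation). Atp5e went from 2632 ± 743 to 1006 ± 182 FPKM. The medians of the 5 complexes were negative under all 4 scalings, from -0.0568 in complex II with TPM scaling to -1.23 in complex IV rescaled. Per library, the median deviation of the 77 subunits from the mean of all libraries was 0.285 to 0.672 in the sham and -0.141 (PS_9552), -0.391 (PS_9553), -0.497 (PS_9561) and -0.989 (PS_9564) in the banded right ventricle. The 734 other transcripts of 500 to 1200 nt moved the same way, from 0.1 to 0.29 in sham and from -0.489 to 0.0664 in banded libraries. With the 2 banded libraries that had an Rn45s value, the complex I median was -0.755 (7 fell) and the complex IV median -0.954 (4 fell).

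**Figure D3:**
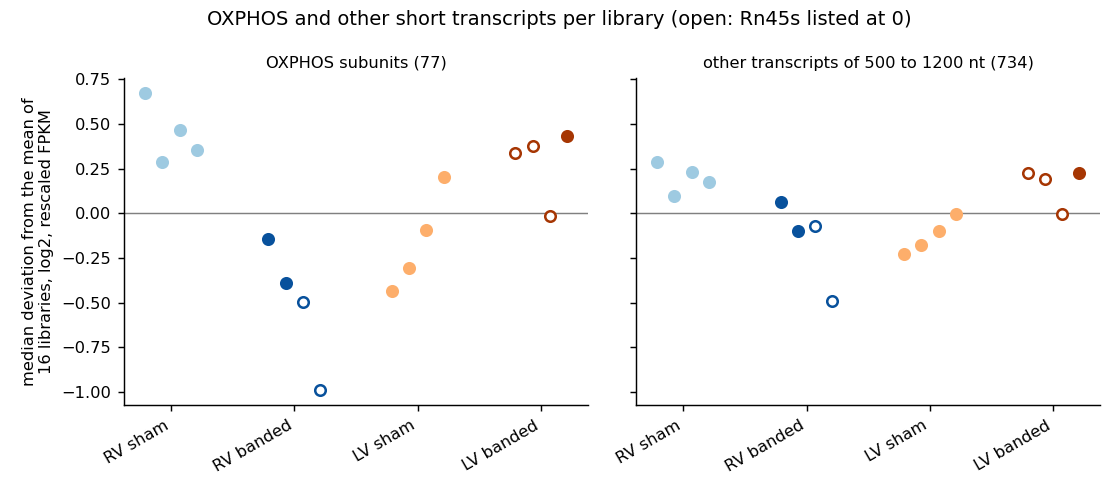
Median log2 deviation of 77 OXPHOS subunit transcripts (left) and of 734 other transcripts of 500 to 1200 nt (right) from the mean of 16 libraries, rescaled FPKM, 1 point per library, open points where Rn45s is listed at 0. OXPHOS lay between 0.285 and 0.672 in the sham and between -0.989 and -0.141 in the banded right ventricle, and between -0.433 and 0.204 in the sham and -0.0171 and 0.433 in the banded left ventricle.

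Part of the genes that use fatty acids fell as well. Of 19 genes of mitochondrial fatty acid oxidation, 9 fell (13 over the list alone, median -0.52 as deposited, -0.71 rescaled, limma camera adjusted p = 1.77e-13, adjusted p = 0.143 with an estimated correlation). Acaa2, the last enzyme of the oxidation cycle, went from 422 ± 50.0 to 144 ± 25.99 FPKM and Etfb, which carries electrons from it, from 658 ± 43.3 to 281 ± 32.7 FPKM (n = 4). Of 12 genes of fatty acid uptake and storage, 7 fell (9 over the list alone, adjusted p = 6.52e-10, adjusted p = 0.143 with an estimated correlation). Ucp3, a mitochondrial carrier, went from 25.2 ± 5.97 to 5.16 ± 1.68 FPKM and Plin5, a lipid droplet protein, from 73.9 ± 10.5 to 30.3 ± 6.70 FPKM. Among mitochondrial ribosomal proteins 15 of 75 fell (16 over the list alone, adjusted p = 4.58e-08, adjusted p = 0.416 with an estimated correlation). Among cytosolic ribosomal proteins 6 of 33 fell (7 over the list alone, adjusted p = 0.000105, adjusted p = 0.449 with an estimated correlation), and the list was not called after correction for transcript length and GC content (median -0.15, adjusted p = 0.0563). In the TCA cycle 3 of 14 fell (3 over the list alone, adjusted p = 0.000617, adjusted p = 0.449 with an estimated correlation), Idh2 by a log2 change of -0.89. The list of ketone and branched-chain amino acid catabolism had 1 rise and 6 falls in 19 (1 and 6 over the list alone, adjusted p = 0.0016, adjusted p = 0.449 with an estimated correlation). Its median was 0.04 as deposited and -0.15 rescaled. Oxct1, which uses ketone bodies, rose by 0.70 and Bcat2, a branched-chain aminotransferase, had a log2 change of -1.06. With TPM scaling, where all genes stood 0.65 higher at the median, the medians of mitochondrial ribosome (0.266), cytosolic ribosome (0.251), TCA cycle (0.324) and ketone catabolism (0.521) were above 0, and those of fatty acid oxidation (-0.031) and uptake (-0.30) below.

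By number of genes, extracellular matrix was the largest list that rose in the banded right ventricle: 29 of 41 passed on both scales (34 over the list alone). The median log2 change was 1.19 as deposited and 1.01 rescaled (limma camera adjusted p = 3.98e-17, adjusted p = 0.164 with an estimated correlation). Sparc, a collagen-binding protein, rose from 97.6 ± 8.39 to 268 ± 23.1 FPKM (n = 4), and Col4a2 of the basement membrane by a log2 value of 1.24. Of 12 hypertrophy and fetal genes, 11 rose (12 over the list alone, adjusted p = 3.14e-11, adjusted p = 0.143 with an estimated correlation). Ctgf, a matricellular growth factor, went from 36.1 ± 11.2 to 234 ± 33.4 FPKM. Of 13 genes of TGF-beta signalling, 8 rose (10 over the list alone, adjusted p = 0.000105, adjusted p = 0.237 with an estimated correlation). The ligand Tgfb2 went from 3.63 to 15.2 FPKM. In the interferon response 5 of 16 rose (6 over the list alone, adjusted p = 0.00247, adjusted p = 0.418 with an estimated correlation), Ifit3 by 1.66. The medians of these 4 lists were above 0 under all 4 scalings.

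Some contractile and electrical genes changed as well. Of 15 cardiac ion channels 5 fell (6 over the list alone, limma camera adjusted p = 0.00143, adjusted p = 0.366 with an estimated correlation). Kcnh2, a repolarizing potassium channel, went from 37.4 ± 2.41 to 18.6 ± 2.81 FPKM and Scn4b, a sodium channel subunit, had a log2 change of -0.77. Of 19 adult sarcomere genes 2 rose and 5 fell (3 and 5 over the list alone, adjusted p = 0.0452, adjusted p = 0.745 with an estimated correlation), and the list was not called after correction for length and GC content (adjusted p = 0.0934). Myom2 and Ttn rose by 1.27 and 0.82. Tnni3, cardiac troponin I, fell from 4967 ± 336 to 2467 ± 403 FPKM (n = 4). The median of the sarcomere list was -0.16 as deposited, 0.334 with TPM scaling and 0.352 after quantile normalization, and that of ion channels 0.215 with TPM scaling. Markers of other cell types were tested beside these groups. Fibroblast markers split, with Pi16 (1.52) and Ddr2 (0.81) up and Scara5 (-1.14) and Htra3 (-0.73) down among 8 (3 up and 2 down over the list alone, adjusted p = 0.467). No call was made for macrophage markers (1 of 15 rose, Cd14 by 1.81, 0 over the list alone, adjusted p = 0.518). Endothelial (1 of 14, Pecam1 by 0.64, 2 up and 1 down over the list alone, adjusted p = 0.265) and mural markers (2 of 10, Cspg4 by 0.72 and Rgs5 by 0.71, 2 over the list alone, adjusted p = 0.416) were not called as lists. Of 5 mesothelial and epicardial markers 2, Upk3b and Msln, fell by log2 changes of -1.86 and -2.10 (2 over the list alone), but the list median was 0.25 as deposited and the list was not called (adjusted p = 0.208). Of 6 atrial markers 2, Stard10 and Kcnj3, had log2 changes of -1.52 and -0.87 (list adjusted p = 0.00998, adjusted p = 0.345 with an estimated correlation), and this list was not called after the same correction either (0.0705).

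In all, 1275 genes rose and 596 fell in the banded right ventricle on both scales, of 12100 tested, and 428 and 208 of these changed at least 2-fold. As deposited 1512 were higher and 596 lower (71.7% higher), rescaled 1308 and 1101 (54.3%), with TPM scaling 5691 and 142 and after quantile normalization 1043 and 1071, all by limma. Among libraries with an Rn45s value, 4 sham and 2 banded, 170 genes were higher and 245 lower, 400 of them shared with the 2108 found in all libraries as deposited. After each library was corrected for its trend with transcript length and GC content, 844 genes were higher and 927 lower, and 1227 of these were shared with the 2108. Without library PS_9561 or PS_9564 the count as deposited was 1205 or 1203, and on both scales 1172 or 1189. Of the 24 named genes that changed on both scales, 17 also passed among the libraries with an Rn45s value. The others had log2 changes there of -3.07 for Ins2 (adjusted p = 0.128), -2.92 for Ins1 (0.246), -2.85 for Iapp (0.0578), -2.82 for Resp18 (0.0644), -2.90 for Hist1h4i (0.145), 0.88 for Myh7 (0.0929) and 2.22 for Acta1 (0.167). With only 2 banded libraries a lost call does not measure the size of a change.

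The left ventricle of banded mice also had more Nppa and Myh7 transcript. Nppa rose from 142 ± 62.7 to 791 ± 281 FPKM (mean ± SD, n = 4 per group, log2 change 2.505 ± 0.33 SE, limma adjusted p = 0.000701). Myh7 rose from 192 ± 27.9 to 664 ± 235 FPKM (1.73, adjusted p = 0.00154), and Postn from 5.93 ± 2.18 to 29.8 ± 18.0 FPKM (1.99, adjusted p = 0.00358). Apod, a lipid-binding apolipoprotein, rose from 3.92 ± 2.36 to 24.0 ± 10.7 FPKM (2.43, adjusted p = 0.00261). Pdk4 fell from 152 ± 39.1 to 66.2 ± 33.4 FPKM, Lgals4 from 30.9 ± 6.76 to 12.2 ± 4.96 FPKM and Prnd, a prion-like protein, from 6.84 ± 1.94 to 2.33 ± 2.08 FPKM (adjusted p = 0.0164, 0.0151 and 0.0339). Ins2 fell from 521 ± 739 to 29.8 ± 12.9 FPKM (adjusted p = 0.00791), with sham libraries from 74.1 to 1620 FPKM. The interferon-induced Ifi27l2a (3.34, adjusted p = 0.0182), the hemoglobin gene Hbb-bt (2.78, 0.0158), Ctla2a (2.38, 0.0138), Gcg (-1.91, 0.0342), Myh6 (0.67, 0.0326), Timp1 (1.42, 0.0474) and Slc2a1 (0.9973, 0.00768) passed as deposited and not rescaled (0.0732, 0.0724, 0.0731, 0.0569, 0.415, 0.208 and 0.155). Nppb (0.76, adjusted p = 0.241), Acta1 (1.01, 0.241), Col1a1 (0.28, 0.271), Col3a1 (0.30, 0.373), Esrra (0.23, 0.338) and Atp2a2 (-0.02, 0.955) did not pass. Cpt1b passed only rescaled (log2 difference -0.55, adjusted p = 0.0252; as deposited -0.15, 0.585).

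Lists of ribosomal proteins and of the proteasome were higher in the banded left ventricle. Of 33 cytosolic ribosomal proteins 15 rose (28 over the list alone as deposited, median log2 difference 1.27 as deposited, 0.88 rescaled, limma camera adjusted p = 6.58e-20, adjusted p = 0.417 with an estimated correlation). Rps14 went from 92.6 ± 19.98 to 303 ± 31.1 FPKM (n = 4). Of 33 proteasome subunits and atrophy ligases 8 rose (22 over the list alone, adjusted p = 4.33e-14, adjusted p = 0.417 with an estimated correlation). Psmc1 went from 22.2 ± 6.07 to 60.9 ± 12.7 FPKM. In glycolysis and glucose uptake 5 of 19 rose (9 over the list alone, adjusted p = 1.53e-07, adjusted p = 0.417 with an estimated correlation), among them Aldoa, aldolase, from 1077 ± 270 to 2205 ± 282 FPKM. In the adult sarcomere 6 of 19 rose (10 over the list alone, adjusted p = 3.19e-06, adjusted p = 0.417 with an estimated correlation). Myl2, the ventricular light chain, went from 6648 ± 1899 to 15810 ± 1822 FPKM. Complex I had 6 rises in 36 (14 over the list alone, median 0.85 as deposited and 0.48 rescaled, adjusted p = 1.75e-11, adjusted p = 0.417 with an estimated correlation). Ndufb9 went from 584.5 ± 245 to 1471 ± 142 FPKM. ATP synthase had 2 in 15 (4 over the list alone, adjusted p = 6.16e-08, adjusted p = 0.417 with an estimated correlation). Of 12 hypertrophy and fetal genes 5 rose (6 over the list alone, adjusted p = 3.26e-05, adjusted p = 0.417 with an estimated correlation). Of 41 matrix genes 4 rose (8 over the list alone, adjusted p = 3.72e-05, adjusted p = 0.44 with an estimated correlation). Bgn, biglycan, went from 66.3 ± 22.1 to 236 ± 90.9 FPKM. The medians of these 8 lists were above 0 under all 4 scalings. Among libraries with an Rn45s value, with 1 banded library, they ranged from 0.124 for the matrix list to 1 for the cytosolic ribosome as deposited. Complex IV had 1 rise in 12, Cox7b (2 over the list alone, adjusted p = 4.75e-05, adjusted p = 0.433 with an estimated correlation). Complex III had 0 in 10 with 3 as deposited (1 over the list alone, adjusted p = 0.00479, rescaled 0.0968). Complex II had a median of 0.17 as deposited and -0.24 rescaled. Fatty acid oxidation had a median of 0.11 as deposited and -0.29 rescaled, -0.0862 with TPM scaling and -0.492 after quantile normalization, and was called only rescaled (adjusted p = 0.000129, lower; as deposited 0.166). Short transcripts were higher and long ones lower in this comparison. The rescaled median was 0.31 at 500 to 700 nt and -0.12 above 4500 nt. With each library corrected for transcript length and GC content complex III (adjusted p = 0.698), complex IV (0.44) and the mitochondrial ribosome (0.95) were no longer called. Complex I (median 0.26, 6 higher, 0.00795), ATP synthase (0.0185) and the cytosolic ribosome (5.89e-17) were called higher, and fatty acid oxidation lower with 5 falls (4.09e-08). With an estimated correlation on the corrected values none of these 4 was called (adjusted p = 0.502, 0.502, 0.0961 and 0.241).

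Some markers of other cell types also changed in the banded left ventricle. Of 4 erythroid markers 1 rose on both scales (4 over the list alone, median 2.05 as deposited and 1.64 rescaled, limma camera adjusted p = 0.00251, adjusted p = 0.417 with an estimated correlation). Hba-a2, a hemoglobin gene, went from 101 ± 22.8 to 342 ± 82.8 FPKM (n = 4). Of 15 macrophage markers 2 rose (3 over the list alone, median 0.79 as deposited and 0.42 rescaled, adjusted p = 0.00277, adjusted p = 0.44 with an estimated correlation). C1qb, a complement subunit, went from 22.15 ± 7.78 to 57.15 ± 10.8 FPKM. Both lists were also called after correction for length and GC content (adjusted p = 0.00299 and 0.000469), but not with an estimated correlation on the corrected values (0.225 and 0.244). Of 6 atrial markers 1 fell, Kcnj3 (1 over the list alone, median -1.42 as deposited, adjusted p = 0.002, adjusted p = 0.417 with an estimated correlation), and the list was not called rescaled (0.0538) or corrected (0.0568).

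**Figure D4:**
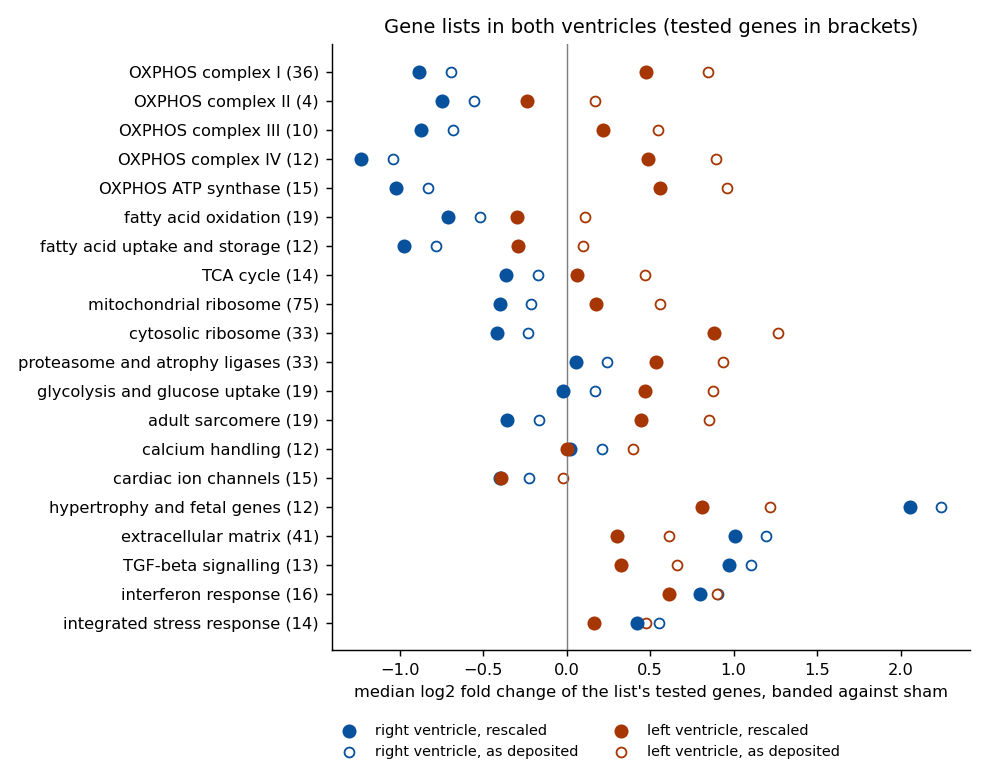
Median log2 fold change of the tested genes of 20 lists, banded against sham, in the right (blue) and left ventricle (brown), filled points rescaled and open points as deposited. The complex I medians were -0.88 in the right and 0.48 in the left ventricle rescaled, and fatty acid oxidation in the left ventricle stood at 0.11 as deposited and -0.29 rescaled.

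In the left ventricle 295 genes rose and 36 fell on both scales, 88 and 13 of them at least 2-fold. As deposited 1725 were higher and 39 lower (97.8% higher), rescaled 295 and 190 (60.8%), with TPM scaling 63 and 13, and after quantile normalization 245 and 266, all by limma. Of the genes that rose in the right ventricle 87 also rose in the left, where 31.1 would be shared if the lists were independent, and of those that fell 19 also fell, where 1.77 would be shared. Another 13 of those that fell in the right rose in the left. The number that independent lists would give was not computed for these, so they are not evidence of opposite responses. The count rested on single libraries. As deposited it was 788 without sham library 2, 981 without 3, 906 without library PS_9552, 885 without PS_9553 and 889 without PS_9561. On both scales it was 92, 45, 95 and 572 without sham libraries 1 to 4 and 166, 54 and 96 without libraries PS_9552, PS_9553 and PS_9561. Prnd lost its call without sham library 1, 2 or 3 or library PS_9552 or PS_9564 (highest adjusted p = 0.117), Lgals4 without sham library 2 or library PS_9561 (0.0602) and Pdk4 without sham library 1 or library PS_9552 (0.0634). Among libraries with an Rn45s value, 4 sham and 1 banded, limma called 3 genes, the microRNA entries Mir207, Mir324 and Mir486, named after their values were seen. None of the 8 named genes that changed on both scales passed there (adjusted p = 0.877 to 1), with 1 banded library and log2 changes of 2.0 for Nppa, 1.3 for Myh7, 0.69 for Postn, 1.64 for Apod, -2.35 for Ins2, -1.88 for Prnd, -0.82 for Lgals4 and -1.79 for Pdk4.

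The response to banding differed between the ventricles in single genes, among them those of the natriuretic peptides. As the right minus the left ventricular log2 change, Nppa differed by 2.43 ± 0.46 (SE, n = 4 per group, limma adjusted p = 0.00404) and Nppb by 2.60 (adjusted p = 0.0151). Thbs4 differed by 2.73 (adjusted p = 0.00223) and Cilp by 1.99 (adjusted p = 0.0294). Ip6k3, an inositol hexakisphosphate kinase of muscle, was at 1.69 ± 0.714 and 6.74 ± 0.397 FPKM in the sham and banded right ventricle and at 6.05 ± 1.29 and 3.87 ± 1.57 FPKM in the left (2.13, adjusted p = 0.00164). Fbp2 (-2.69), Dhrs7c, a dehydrogenase of the sarcoplasmic reticulum (-2.70), Penk, proenkephalin (-2.69), all with adjusted p = 0.00069, and Cdo1, cysteine dioxygenase (-2.74, adjusted p = 0.0021) differed the other way. Dhrs7c went from 73.9 ± 15.6 to 20.7 ± 5.39 FPKM in the right and from 40.6 ± 14.1 to 76.1 ± 21.9 FPKM in the left ventricle. Fbp2 stood at 10.7 ± 1.60 and 10.2 ± 2.11 FPKM in the left. Cox7c (-2.75, adjusted p = 0.0428, rescaled 0.0928) and Esrra (-1.05, 0.00689, rescaled 0.0531) passed only as deposited, and Col1a1 (0.79, 0.054, rescaled 0.0417), Col3a1 (0.97, 0.0738, rescaled 0.0399) and Postn (1.59, 0.0996, rescaled 0.0384) only rescaled. Myh7 (-0.42, adjusted p = 0.655), Pdk4 (-0.38, 0.746) and Ppargc1a (0.24, 0.834) did not pass.

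All 5 OXPHOS lists were called for the difference between ventricles at the preset correlation and none with an estimated one. In complex I 22 of 36 had a lower response in the right ventricle on both scales (29 over the list alone, median difference -1.56 as deposited, -1.34 rescaled, limma camera adjusted p = 3.8e-29, adjusted p = 0.0949 with an estimated correlation), with Ndufs6 at -2.43. ATP synthase had 12 of 15 (15 over the list alone, adjusted p = 2.01e-19, adjusted p = 0.0949 with an estimated correlation). Atp5e was at -2.41. Complex IV had 10 of 12 (12 over the list alone, adjusted p = 2.05e-15, adjusted p = 0.0949 with an estimated correlation). Complex III had 5 of 10 (7 over the list alone, adjusted p = 3.67e-08, adjusted p = 0.183 with an estimated correlation). Complex II had 1 of 4 (2 over the list alone, adjusted p = 0.000325, adjusted p = 0.103 with an estimated correlation), where the median was -0.77 as deposited and 0.182 after quantile normalization. Cytosolic ribosomal proteins had 19 of 33 (25 over the list alone, adjusted p = 8.44e-22, adjusted p = 0.0982 with an estimated correlation). Fatty acid oxidation had 6 of 19 (6 over the list alone, adjusted p = 5.85e-08, adjusted p = 0.325 with an estimated correlation). Etfb was at -1.99. The adult sarcomere had 8 of 19 (12 over the list alone, adjusted p = 6.34e-07, adjusted p = 0.325 with an estimated correlation), with Tnni3 at -2.18 and Myl2 at -2.15. The sarcomere median was -0.85 as deposited and 0.115 after quantile normalization. Matrix genes differed upward, 4 of 41 (8 over the list alone, median 0.56 as deposited, adjusted p = 1.58e-08, adjusted p = 0.325 with an estimated correlation), with Col4a1 at 0.98 and Col8a1 at 1.72. The median of all genes was -0.0661 as deposited, 0.107 rescaled and 0.48 with TPM scaling. Transcript length moved with this comparison, from a rescaled median of -0.42 at 500 to 700 nt to 0.36 above 4500 nt. After correction for length and GC content the medians were -0.67 in complex III, -1.07 in complex IV and -0.91 in the cytosolic ribosome, against -1.02, -1.64 and -1.42 rescaled. Over all genes 64 differed upward and 418 downward on both scales, 64 and 669 as deposited (8.73% upward), 261 and 426 rescaled (38.0%), 726 and 28 with TPM scaling and 255 and 266 after quantile normalization. The count as deposited, 733, was 448 without left library PS_9552, and that on both scales, 482, was 274 without it, 321 without left library PS_9564, 289 without left sham library 1 and 310 without left sham library 3. Cilp lost its call without right PS_9561 or PS_9564, left sham 1, 2 or 3 or left banded PS_9552 or PS_9564 (highest adjusted p = 0.0751). Among libraries with an Rn45s value, which hold 1 left banded library, Penk differed by -3. Other genes named above as passing on both scales had differences there such as 3.18 for Thbs4, 2.98 for Nppa, -2.86 for Dhrs7c, -2.93 for Fbp2 and -2.09 for Cdo1. Most of the named genes lost their call there, where a test that rests on 1 library decides little. Blocked by library number the count was 475 as deposited and 206 rescaled.

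**Figure D5:**
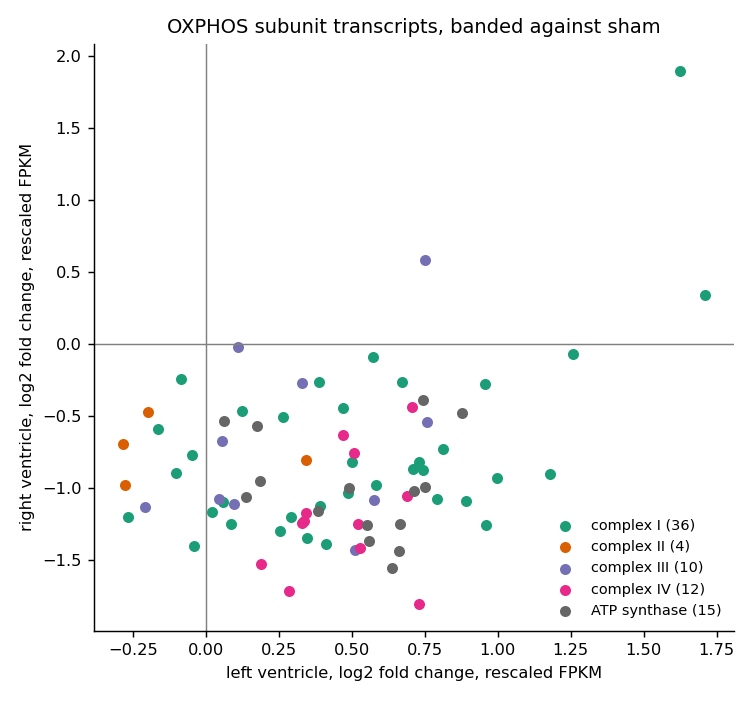
Log2 fold change of each of 77 OXPHOS subunit transcripts, banded against sham, in the left (horizontal axis) and right ventricle (vertical axis), rescaled FPKM, coloured by complex. The median of the 77 was 0.47 in the left and -0.979 in the right ventricle, with complex II in the left at 0.17 as deposited and -0.24 rescaled, and Ndufb4 of complex I stood apart in the right with a log2 difference of 1.98 as deposited (adjusted p = 0.0726).

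Sham right and left ventricles differed in an imprinted RNA, endocrine transcripts and a stretch-responsive gene. H19, an imprinted noncoding RNA, was at 15.9 ± 5.36 FPKM in the right and 3.90 ± 1.79 FPKM in the left ventricle (mean ± SD, n = 4 per group, log2 difference 1.80 ± 0.32 SE, limma adjusted p = 0.0125). Ankrd1 was lower in the right, at 389 ± 170 against 1103 ± 361 FPKM (-1.55, adjusted p = 0.0217). So were Isoc1, an isochorismatase domain protein, at 3.46 ± 1.58 against 10.8 ± 1.57 FPKM (-1.46, adjusted p = 0.0125), Gnb3, a G protein subunit (-1.51, 0.0192), Krt222 (-1.48, 0.0259) and Smim13 (-1.42, 0.0217). Iapp (3.41, adjusted p = 0.00791), the granins Chga (1.97, 0.0211) and Chgb (1.66, 0.0174) and the chemokine Ccl6 (2.02, 0.0217) were higher in the right, and Esrra was at 90.7 ± 11.04 against 53.1 ± 6.44 FPKM (0.76, 0.0163). Over the 16 libraries Iapp, Chga and Chgb moved with the insulin transcript Ins2 (Spearman rho 0.874, 0.935 and 0.879). The source of these transcripts is open, so their difference may not be one of the ventricles themselves. The natriuretic peptide genes Nppa (-1.08, adjusted p = 0.0683) and Nppb (-1.53, 0.0512) did not pass as deposited, and Nppb did rescaled (0.0316). In complex I 7 of 36 were higher in the right (20 over the list alone, limma camera adjusted p = 2.37e-11, adjusted p = 0.819 with an estimated correlation). In cytosolic ribosomal proteins 8 of 33 were higher (14 over the list alone, adjusted p = 5.83e-08, adjusted p = 0.819 with an estimated correlation). The medians were 0.65 and 0.59 as deposited and 0.0931 and 0.0371 with TPM scaling, where the median of all genes was -0.467. After correction for transcript length and GC content they were 0.33 with 3 genes higher and 0.26 with 1, against 0.59 and 0.56 rescaled. In all 308 genes were higher and 161 lower in the right on both scales, 357 and 161 as deposited (68.9% higher), 426 and 617 rescaled (40.8%), 38 and 2989 with TPM scaling and 350 and 513 after quantile normalization. The 518 as deposited became 322 without right sham library 1 and 111, 306 and 80 without left sham libraries 1, 2 and 3, and the 469 on both scales became 301, 100, 293 and 80 without the same libraries. Blocked by library number the count was 131 as deposited and 377 rescaled. Calls of Ccl6, Ankrd1, Smim13 and Esrra were lost without left sham library 1 or 3, of Krt222 without 1, 3 or 4, of Gnb3 without 1, and of Chga and Chgb without 3 (adjusted p up to 0.0728). Esrra was not called after correction for transcript length and GC content (adjusted p = 0.126).

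In banded mice Thbs4 was higher in the right ventricle than in the left, and Dhrs7c and Ces1d were lower. Thbs4 was at 25.2 ± 8.85 FPKM in the right and 5.33 ± 2.45 FPKM in the left (n = 4 per group, log2 difference 2.07 ± 0.33 SE, limma adjusted p = 0.00463). Cilp was at 11.1 ± 2.85 and 3.61 ± 2.97 FPKM (1.61, adjusted p = 0.0246) and Ltbp2, a matrix protein of the family named latent TGF-beta binding proteins, at 7.84 ± 1.18 and 2.60 ± 1.66 FPKM (1.41, 0.0205). Nppa was at 1976 and 791 FPKM (1.35, 0.0333) and Col1a1 at 101 and 59.6 FPKM (0.77, 0.0177). Dhrs7c (-1.82) and Ces1d, a carboxylesterase (-1.78), both with adjusted p = 0.00253, Rwdd1 (-1.67, 0.0288) and Myh6, at 1741 ± 482 against 3169 ± 648 FPKM (-0.88, 0.0239), were lower in the right. Gdf15 (1.91, adjusted p = 0.042), Ndufa12 (-1.87, 0.0345), Rps20 (-1.71, 0.0173) and Atp2a2 (-0.78, 0.0349) passed only as deposited. In complex I 12 of 36 were lower in the right on both scales (28 over the list alone, limma camera adjusted p = 2.04e-29, adjusted p = 0.101 with an estimated correlation). In cytosolic ribosomal proteins 11 of 33 were lower (23 over the list alone, adjusted p = 1.96e-22, adjusted p = 0.101 with an estimated correlation). In calcium handling 2 of 12 were lower, Hrc (-1.19) and Pln (-0.89) (5 over the list alone, adjusted p = 8.2e-05, adjusted p = 0.212 with an estimated correlation). In the matrix list 3 of 41 were higher (14 over the list alone, adjusted p = 8e-13, adjusted p = 0.202 with an estimated correlation). In all 22 genes were higher and 168 lower in the right on both scales, 23 and 350 as deposited (6.17% higher), 82 and 174 rescaled (32.0%) and 100 and 92 after quantile normalization. With TPM scaling limma called 0, where the fit as deposited had 1858 at an unadjusted p under 0.05 and 1281 genes had groups that did not overlap as deposited, against 2.86% of genes by chance. That share holds for equal scale factors, and these were 0.896 to 1.26 in the right and 0.9755 to 1.285 in the left banded libraries. Among libraries with an Rn45s value, 2 right and 1 left, it called 4, the microRNA entries Mir1943, Mir207, Mir324 and Mir486, named after their values were seen. Blocked by library number the count was 208 as deposited and 12 rescaled. The 373 as deposited became 157, 120 and 227 without right libraries PS_9552, PS_9553 and PS_9564 and 117, 144 and 204 without left libraries PS_9552, PS_9553 and PS_9561. The 190 on both scales became 109, 55, 66 and 48 without right libraries PS_9552, PS_9553, PS_9561 and PS_9564 and 25, 55, 116 and 43 without the left ones in the same order. Thbs4, Dhrs7c and Ces1d kept their calls without any single library. Cilp lost its call without any right library or left PS_9552 or PS_9564 (highest adjusted p = 0.117) and Nppa without any right library or left PS_9552, PS_9561 or PS_9564 (0.127). Rwdd1 lost its call without right PS_9552, PS_9553 or PS_9564 or left PS_9552, PS_9553 or PS_9561 (0.105). Myh6 lost its call without right PS_9552 or PS_9553 or left PS_9552 or PS_9561 (0.103), Col1a1 without right PS_9552 or PS_9553 or left PS_9552 (0.081) and Ltbp2 without either library PS_9552 (0.0918). Rwdd1 (0.0959), Ltbp2 (0.0772) and Col1a1 (0.0739) were not called after correction for length and GC content.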

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

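The tests of scale by Rn45s listing, of a fixed amount of Ins2 fragments and against matched lists on corrected values were chosen only after the result was seen.

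Most transcripts were higher in banded than in sham libraries as deposited, by a median log2 difference of 0.26 in the right and 0.33 in the left ventricle. Within the banded libraries of each ventricle, those listed at 0 for Rn45s had the highest scale factors (one-sided exact permutation p = 0.0417, the smallest that 24 arrangements can give), a relation already seen when it was tested, so the p is no evidence of its own. A rise of most transcripts with banding was to put the banded libraries with an Rn45s value above every sham library, and with both ventricles pooled their highest scale factor, 0.976, was below the highest sham one, 1.02, which spoke against it. Compared within ventricles, a change made later still, the right ones were at 0.896 and 0.931, inside the sham range of 0.871 to 1.02, but the only left one, at 0.976, was above its sham range of 0.840 to 0.974. The banded libraries with an Rn45s value (0.896 to 0.976) all lay below the banded ones listed at 0 (1.22 to 1.28). This gap inside the banded libraries argues against banding as the whole cause. Whether a smaller rise with banding lies beside a difference in scaling cannot be told here, since all 5 libraries listed at 0 are banded and 3 banded libraries are left.

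OXPHOS transcripts were lower in the banded right ventricle and higher in the banded left. After each library was corrected for its trend with transcript length and GC content the right ventricular median of the 77 subunits was -0.708 (before, -0.979). It lay below 10000 lists matched for length and level on the same corrected values (median -0.261, 5th percentile -0.374), which argues against the trend as the whole cause. The matched lists were themselves still below 0 after the correction. Draws of fragments at the estimated depths with no gene changed gave medians no lower than -0.0645, a simulation, while without the shallowest sham library, 2, the observed median was -1.01. In the left ventricle the correction left 0.158 of 0.47, within the matched lists (median 0.178), so the rise of the 77 together may be a length and GC trend, but complex I (adjusted p = 0.00795) and ATP synthase (0.0185) stayed called at the preset correlation and not with an estimated one (0.502 for both), which leaves these open. An effect of banding on these transcripts in the right ventricle remains a hypothesis, found and tested on the same data.

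Ins2, Ins1, Gcg and Iapp, hormone genes of pancreatic islets, fell in the banded right ventricle, and of these 4 only Ins2 fell in the left on both scales, while Cpe, another islet gene, rose in the right from 52.7 to 84.7 FPKM. Over the 16 libraries, islet genes not looked at before had a median Spearman rho with Ins2 of 0.257 (3 of 16 genes above 0.5). Most of them did not pass the filter (Nkx2-2 was above 0 in 1 library and Ucn3 in 2), which limits this median. Among those looked at before, rho was 0.655 to 0.965 for Ins1, Gcg, Iapp, Chga, Chgb, Scg2 and Resp18. It was 0.167 to 0.451 for Pcsk1n, Sst, Ppy and Pyy and -0.793 for Ttr, which was listed at 0 in all right ventricular sham libraries. RNA of islet tissue was thus neither shown nor excluded. A fixed number of foreign fragments per library would hold Ins2 FPKM times depth nearly constant, but it varied 8.98-fold within the left ventricular sham group. Expression in the heart and RNA carried over from other samples possibly remain as sources and were not tested.

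Other splits of the same libraries were fitted. In the right ventricle 1 of 35 splits, the real one, gave as many genes (2108, highest other 9), in the left 1 of 35 (1764, highest other 1), between sham ventricles 1 of 35 (518, highest other 7) and between banded ventricles 1 of 35 (373, highest other 2). A chance division of the libraries is thus unlikely for these counts, though 1 of 35 is the smallest share such splits can give. The splits do not tell an effect of banding from scale factors and depth, which differ between the same groups. For the difference between ventricles 4 of 100 gave as many as 733, the highest other 3464. That split keeps the right ventricular labels and exchanges the left ones, which adds the 2 effects of banding, so such splits are no measure of chance for a difference and do not exclude it, though a share this low was set beforehand to do so.

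Single libraries stood far from the other 3 of their group in 22 of 216 groups tested, where chance gives about 1 in 20. In right ventricular sham libraries these were Thbs4 at 0.3846 FPKM and Hbb-bt at 8.713 in library 1, Ctla2a at 10.94 in 3 and Acta1 at 497.3 in 4. In right ventricular banded libraries they were Prnd at 2.237 FPKM in PS_9552, Postn at 83.77 in PS_9561 and Chgb at 2.455 in PS_9564. In left ventricular sham library 1 they were Ankrd1 at 1638 FPKM, Ins2 at 1620, Ins1 at 438.7, Resp18 at 5.86, Ppargc1a at 15.77 and Smim13 at 7.024, and in library 4 Acta1 at 343.3 and Esrra at 62.65. In left ventricular banded libraries they were Atp2a2 at 1766 FPKM, Ckmt2 at 1877 and H19 at 45.13 in PS_9552, Ins1 at 4.509 in PS_9553, Smim13 at 8.213 in PS_9561, and Hist1h4i at 0 and a scale factor of 0.9755 in PS_9564.

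The effect of banding differed between the ventricles by the limma test of the difference, on both scales, in 10 of the genes chosen by size or fixed in advance for either ventricle or their difference. Genes chosen by size for the difference had to pass this test as deposited, so the count is no separate result. The right minus left log2 effect was 2.733 for Thbs4, 2.603 for Nppb, 2.433 for Nppa, 2.131 for Ip6k3, 1.993 for Cilp and 1.679 for Ankrd1, and -2.741 for Cdo1, -2.703 for Dhrs7c, -2.693 for Fbp2 and -2.69 for Penk.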

How the results depend on the processing

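Alternatives chosen only after the data were seen were library weights, the rescalings other than the plain one, the length and GC correction and the fits to libraries with an Rn45s value. Counts are of genes changed, against 2108 in the right ventricle, 1764 in the left, 733 for their difference, 518 in sham and 373 in banded mice. All 5 counts stayed within 1.5 times with a pseudocount of 0.1 or 5, no filter, a filter at 5 FPKM and a robust prior. With TPM scaling they were 5833 (right), 76 (left), 3027 (sham) and 0 (banded) by limma, rescaled 485 (left) and 1043 (sham), and by quantiles 511 (left), 863 (sham) and 192 (banded). From the libraries of a comparison alone they were 881 (right), 2780 (left) and 50 (sham), with no such fit for the difference. Blocked by library number they were 475 (difference), 131 (sham) and 208 (banded), and with library weights 1062 (right), 5613 (left), 1219 (difference) and 2036 (banded). Rescaled, they were 648 (left) and 965 (sham) with a filter at 5 FPKM, 506 (left) and 1080 (sham) without small RNA, 431 (left), 462 (difference) and 190 (banded) after length and GC correction, and 481 (left), 206 (difference) and 12 (banded) with the block. With an Rn45s value only, which leaves fewer libraries and 1 banded left library assumed to vary like the others, they were 415 (right), 3 (left), 9 (difference), 323 (sham) and 4 (banded). As deposited, groups did not overlap for 2802 genes (left, 2688 of them higher in banded), 1385 (sham) and 1281 (banded). Chance gives 2.86% where libraries have equal scale factors. All left banded scale factors (from 0.9755) were above all left sham ones (to 0.9736), which by itself can separate the groups. Omitting each library in turn gave 1203 to 2351 (right), 788 to 2394 (left), 448 to 929 (difference), 80 to 633 (sham) and 117 to 461 (banded). The cause of these shifts was not tested, also where fewer libraries were fitted. Of 240 list tests 106 were called, and 0 by camera with an estimated correlation (lowest adjusted p = 0.0949), 95 by fry and 98 rescaled. Direction reversed in the left ventricle for fatty acid uptake and storage (adjusted p = 0.6866) and hypoxia and angiogenesis (0.04492) by fry, and for mitochondrial protein import (0.5074) and the creatine and adenine nucleotide shuttle (0.9538) after length and GC correction; the cause was not tested. No named gene past the threshold in the fit as deposited or in the alternative changed sign between them. Depth limits genes near 1 FPKM, where the shallowest library holds an estimated 0.886 fragments of a median-length transcript.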
